A study of Drosophila melanogaster with 4 samples.

How the data were processed

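Binding of the Drosophila melanogaster homeodomain protein Distal-less (Dll), a transcription factor required for the distal parts of the limbs, was assayed by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in white prepupae, the short stage at the start of metamorphosis. Per the labels, chromatin came from the strain Y cn bw sp. The precipitating antibody was a rabbit polyclonal serum, affinity-purified, raised against Dll. The series holds 4 libraries, namely 2 replicates of Dll ChIP DNA and 2 replicates of input DNA, which is sheared chromatin that was not precipitated. Nothing in the labels says whether the replicates came from separate collections of animals.

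The processed data analysed here were 1 list of peaks for the whole series, with 0 values per library. Per the submitters' processing notes, CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2 were used with genome build BDGP 5. Versions of BWA and MACS2, the calling threshold, the filters and whether replicates were pooled before calling are not given in the sources used here. Per the file headers, the list is in GFF version 3, a format that counts positions from 1, on FlyBase release 5. Each peak has a start, an end and 1 score that was deposited under the name of the peak caller MACS without naming its scale. The score is the authors' own value for each peak, and it was used only within the list, to rank, describe and filter peaks, to compare medians between sets of peaks and to correlate peaks. As its scale is not named, a difference in score is no fold of binding. The list gives no counts or read totals, so the depth of each library is unknown. No confidence interval for a peak's score, no spread between replicates and no comparison of ChIP with input could be computed. Peaks that a different depth would add or remove cannot be recovered from a list already cut at a threshold.

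The analysis was planned before the data were examined, as 7 results. Peak number, width and strength and the density of peaks by chromosome arm were run. The other 5 results were not run: peak positions relative to genes, peak strength by class of position, 23 lists of genes, the number of peaks per gene, and the occurrence of homeodomain motifs. They need sequence or annotation of release 5, and the gene table at hand is of release 6, whose coordinates cannot be used for these peaks. The list itself names no gene. For that case the rule set beforehand was to name no gene near a peak and to name the 10 highest and the 10 widest peaks by position. Statements on spacing, on neighbours, on windows along the arms, on the centromere side, on scores by arm or class of score, on the top 10% and 1%, and on regions other than those 20 peaks were chosen after the list was seen.

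Widths were computed as end minus start plus 1. Arms were 2L, 2R, 3L, 3R, 4 and X. Because arm lengths of release 5 were not used here, the length of an arm was taken as the span from its first to its last peak. Each arm's share of peaks was compared with its share of the summed spans by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 6 arms, and its ratio of observed to expected peaks has an exact 95% Clopper-Pearson interval. These tests and intervals treat peaks as independent and cover counting error only. Since peaks lie in clusters, their p-values are too small, and each large arm was therefore also compared over whole windows of 1 Mb by a two-sided permutation test of the difference in means (100000 resamples). Windows next to each other are not fully independent either. These windows were laid from the low-coordinate end of each span, and the part window left at the high end, which on 2L, 3L and X is the centromere side, was left out. For the comparison of the centromere side they were laid from the centromere end of the span instead, a choice made after the values on the first grid were seen. Windows on the centromere side were compared with the others by an exact permutation test, two-sided, which counts every choice of as many windows. Medians of score and width were compared by two-sided permutation tests (100000 resamples), adjusted over 10 comparisons for those of X, 4, U, Uextra and mapped heterochromatin with the peaks of 2L, 2R, 3L and 3R. Correlations of neighbouring scores were tested with 10000 permutations, for which the smallest p is 0.0001, or 0.00013 after adjustment over 4 classes of distance.

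Spacing was tested by placing the peaks of each large arm at random 1000 times, with their own widths, without overlap and at least 50 bp apart, which is the shortest gap in the list. The test is one-sided. The smallest p-values that these procedures can give are 0.001 for 1000 placements and 1e-05 for 100000 resamples. Peaks are not replicates of an experiment, so every p-value describes this 1 list and not the variation between animals or libraries. The scripts were tested on simulated lists of 15645 peaks. With X given 0.6 times the density of the other arms, for which the true ratio of observed to expected peaks is 0.648, the test returned 0.661. With uniform placement the spacing ratio was 1.01, and with 50% of peaks moved next to the peak before them it was 1.30. Alternatives were the 50% and the 25% of peaks with the highest scores, peaks within 1000 bp merged into 1 region, base pairs in place of peak number, and the outer 1000000 bp of each arm left out. Windows in place of the binomial test, other window sizes, other gap lengths and other ways of placing peaks were added after the list was seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.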

Results

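Dll was profiled by ChIP-seq in white prepupae with 2 ChIP libraries and 2 input libraries, and the outcome is 1 list of 16117 peaks, with a single score for each. The question put to these data is therefore where in the genome the antibody against Dll enriched chromatin at this stage. There are no values for single libraries, so depth is unknown and no error between replicates can be given. The spreads below are between peaks, between windows of the genome or, for shares of gaps, between random placements.

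The 16117 peaks covered 9.41 Mb. Their median width was 432 bp (interquartile range 295 to 678 bp), and the widest peak covered 11207 bp. Scores had a median of 17.27 (interquartile range 11.72 to 35.28) and ran from 5.78 to 939.07. Peaks with higher scores were wider. The median width was 1039 bp in the 1612 peaks of the top 10% and 1335 bp in the 162 peaks of the top 1%. Across all peaks, the Spearman correlation of width with score was 0.708 and the Pearson correlation of their log10 values was 0.702. These are correlations across peaks, which are not independent replicates. Of all peaks, 83.2% shared their exact score with at least 1 other peak.

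The highest peak of the list lay on 2L, at 14489974 to 14491294, with a score of 939.07 over 1321 bp. The second and the fifth lay close to each other on the same arm. One of them spanned 3544982 to 3545954 with a score of 820.91, and the other spanned 3578285 to 3581307 with a score of 743.91. On 2R, the peak at 19553970 to 19556612 scored 816.98. Also among the 10 highest were the peaks of 2R at 9812776 to 9813388 (score 609.11), at 4535960 to 4538062 (596.4) and at 8902961 to 8903692 (583.22). On 3R, the peaks at 22055223 to 22058374 and at 27538184 to 27539999 scored 761.91 and 741.46. The last of the 10, on 3L at 17556421 to 17557381, scored 581.89. None of the 10 highest peaks was on X or 4.

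No difference in the density of surrounding peaks was detected for high peaks. The 162 peaks in the top 1% had 10.9 ± 5.8 other peaks within 25 kb (mean ± SD), and the other 15483 peaks of the arms had 10.6 ± 6.1 (permutation test, two-sided, p = 0.55). Among the 10 highest, the number of other peaks within 25 kb went from 1 for the peak of 3R at 22055223 to 22 for the peak of 2R at 4535960.

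The widest peaks were different ones, and 0 of the 10 widest were among the 10 highest. The widest, on 2R at 20726240 to 20737446, covered 11207 bp with a score of 135.37. The peaks ranked 3 and 8 by width lay beside it, at 20706194 to 20713456 (7263 bp, score 64.05) and at 20691933 to 20697318 (5386 bp, score 122.7). From the start of the last of these to the end of the widest, 12 peaks covered 84.1% of 45.5 kb, with a median width of 2212 bp. This stretch ends 379 kb before the last peak of 2R, at the distal end of the arm. The gene for Dll lies in the distal part of 2R, but whether the stretch includes it was not determined, because no release 5 annotation was used here. The stretch was chosen after its values were seen. Over a grid of 100 kb windows, the window of 2R from 20659208 to 20759207 had the highest share of its length in peaks, 66.8%. The next window, on 2R from 7359208 to 7459207, reached 44.0%, and the mean of the 1184 windows was 7.76% ± 6.95 (SD).

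**Figure D1:**
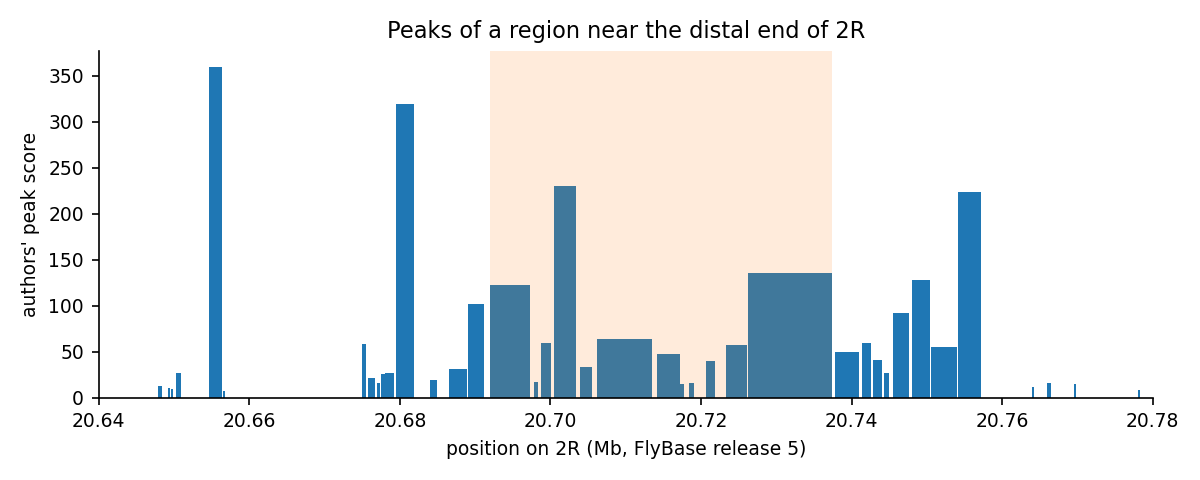
Peaks near the distal end of 2R. The x axis gives the position on 2R in Mb (FlyBase release 5), each bar is 1 peak drawn over its own width, and the y axis gives the score written by the authors' caller. The shaded 45.5 kb stretch holds 12 peaks that cover 84.1% of it, 3 of them among the 10 widest of the list.

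The other wide peaks were spread over 5 arms. On 3L, a peak of 8278 bp lay at 662013 to 670290 (score 222.65) and one of 5605 bp at 10845486 to 10851090 (331.98). On 2L, a peak of 6054 bp lay at 1061121 to 1067174 (178.52). On 2R, peaks of 5705 bp and 5067 bp lay at 18127288 to 18132992 (357.05) and at 13722258 to 13727324 (164.79). On X, a peak of 5535 bp lay at 18430551 to 18436085 (250.59), and on 3R a peak of 5173 bp lay at 21827980 to 21833152 (166.89).

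Peaks were not spread evenly over the chromosomes. X held 1853 peaks, or 82.7 per Mb, against 124.6 per Mb on 2L, 139.8 on 3L, 148.2 on 3R and 159.6 on 2R. The small chromosome 4, most of which is packed as heterochromatin, held 30 peaks, or 25.4 per Mb. Relative to its span, X had 0.634 times the expected number of peaks (95% exact interval 0.607 to 0.661, exact binomial test, adjusted p = 1.4e-118), and chromosome 4 had 0.195 times (0.131 to 0.278, adjusted p = 5.6e-34). For chromosome 4 the ratio was 0.301 in the highest 50% of peaks by score and 0.341 in the highest 25% (exact binomial test, adjusted p = 2.7e-12 and 1.3e-05). The ratio of 2R was 1.22 (1.19 to 1.26, exact binomial test, adjusted p = 1.8e-35). Ratios were 0.955 (0.923 to 0.987) for 2L, 1.07 (1.04 to 1.103) for 3L and 1.14 (1.11 to 1.17) for 3R.

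Over 1 Mb windows, X held 84.0 ± 30.8 peaks per window (SD, n = 22 windows) and the arms 2L, 2R, 3L and 3R held 144.3 ± 47.7 (SD, n = 94 windows). X was lower by a factor of 0.582 (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). The sex of the animals and the share of reads on X were not examined, so fewer peaks on X need not mean less binding. 2R, with 159.9 ± 55.0 peaks (SD, n = 21 windows), was above the other large arms, which had 126.9 ± 48.1 (n = 95 windows, permutation test, adjusted p = 0.016). Those other windows include the windows of X, which lower their mean. The means of 2L, 3L and 3R were 129.0, 141.8 and 147.0, and 2R was not tested against these arms alone. The differences of 2L, 3L and 3R from the other large arms did not pass the permutation test over windows (adjusted p = 0.69, 0.42 and 0.16). Their exact binomial tests over peaks, which ignore clustering, did pass (adjusted p = 0.0059, 9.8e-06 and 5.4e-20). Those tests also include X and chromosome 4 in the expected share.

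**Figure D2:**
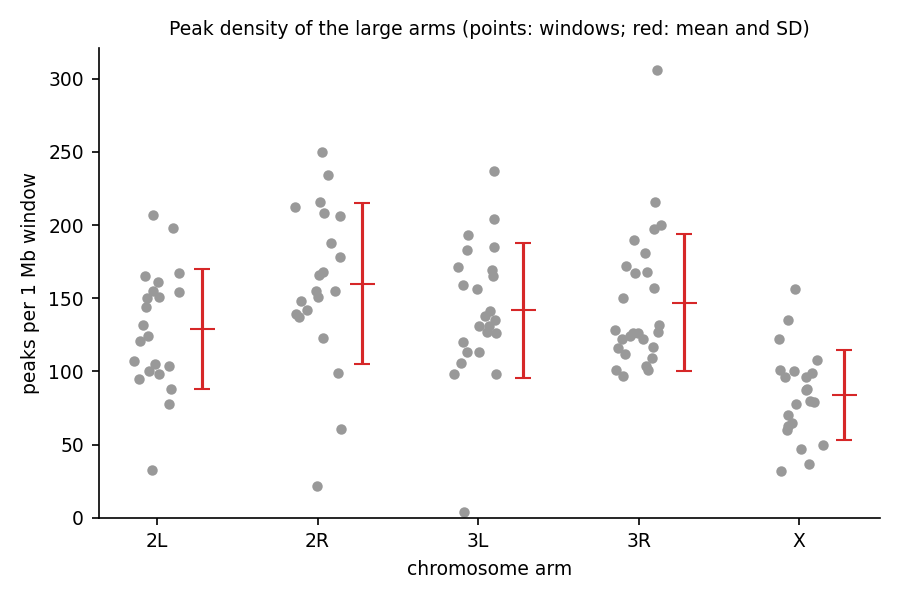
Peak density of the 5 large arms. Each grey point is the number of peaks (y axis) in 1 window of 1 Mb of the arm on the x axis, and the red bar gives the mean and SD over windows. X has a mean of 84.0 peaks per window, below the means of 2L, 2R, 3L and 3R.

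The deficit of X was smaller among peaks with high scores. When the arm peaks were divided into 4 classes of score, X had 0.561 times the expected peaks in the lowest class (95% exact interval 0.511 to 0.615), 0.539 in the next, 0.618 in the third and 0.815 (0.755 to 0.877) in the highest. On chromosome 4, with 30 peaks in all, the ratios of the 4 classes were 0.104, 0.0792, 0.255 and 0.337 (0.180 to 0.576 in the highest). In the top 10% of the list the ratio of X was 0.902 (0.805 to 1.01, exact binomial test, p = 0.066), and in the top 1% it was 0.925 (0.631 to 1.28, p = 0.76). Over windows, the peaks of X in the highest class numbered 27.0 ± 10.95 per Mb (SD, n = 22 windows) against 34.6 ± 12.8 on 2L, 2R, 3L and 3R (n = 94 windows, permutation test, p = 0.011). The highest class made up 31.7% ± 6.77 of the peaks of an X window and 24.2% ± 5.83 of those of the other arms (SD, permutation test, two-sided, p = 1e-05, the smallest it can give). The median score of X peaks, 19.73 (interquartile range 12.23 to 47.93), was above that of the peaks of 2L, 2R, 3L and 3R, 16.70 (permutation test over peaks, adjusted p = 5e-05). Their median widths were 431 and 436 bp (permutation test, adjusted p = 0.72). The 30 peaks of chromosome 4 had a median score of 30.4 (interquartile range 17.6 to 54.5), also above the 16.70 of 2L, 2R, 3L and 3R (permutation test, adjusted p = 0.0072). Their median width, 591 bp, was above 436 bp as well (permutation test over peaks, adjusted p = 0.034). Many of these 30 peaks lay close together near the high-coordinate end of the chromosome. Both tests treat them as independent, so their p-values can be too small.

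**Figure D3:**
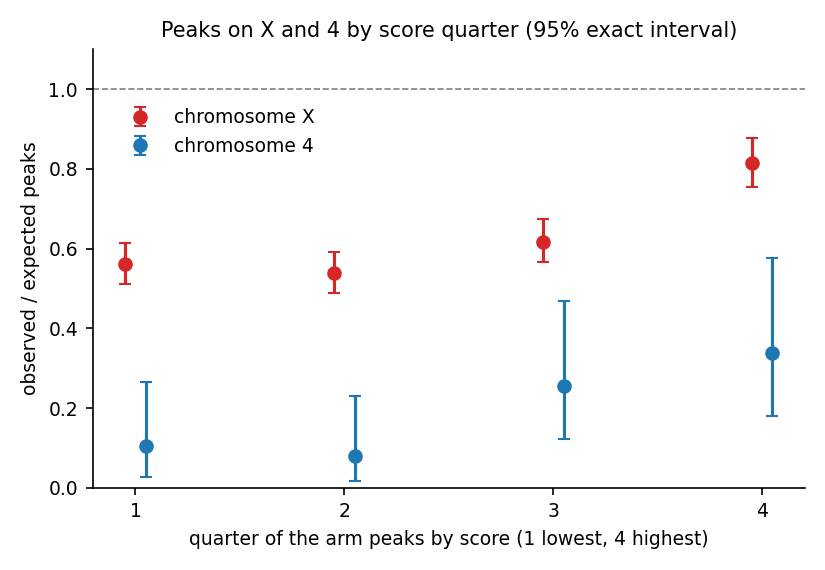
Observed over expected number of peaks (y axis) on X and on chromosome 4 in 4 classes of peak score (x axis, lowest to highest). Points are ratios, bars are 95% exact intervals for counting error only, and the dashed line marks equality. The ratio of X is 0.561 in the lowest class and 0.815 in the highest.

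Peaks were sparse next to the centromere on 2L, 2R, 3L and X. The last 1 Mb of the peak span on the centromere side held 6 peaks on 3L, 16 on X, 22 on 2R and 25 on 2L, against 181 on 3R. Whether reads could be placed in this sequence was not examined, so fewer peaks there need not mean less binding. With windows laid from the centromere end, the 2 nearest windows of each large arm held 70.5 ± 61.3 peaks (SD, n = 10 windows), against 137.0 ± 47.1 in the others (n = 106 windows, exact permutation test, two-sided, p = 8e-05). With 3 windows per arm the means were 100.6 and 135.8 (exact permutation test, p = 0.014). This grid was chosen after the values of a grid laid from the low-coordinate end were seen. On that grid the 2 windows gave a ratio of 0.653 (exact permutation test, p = 0.0046), but the difference did not pass without 2R (0.785, p = 0.12) or with 3 windows per arm (0.857, p = 0.17). The longest stretch without a peak on the large arms, 464 kb, lay at 23149659 to 23614011 on 3L. The first peaks of 3L and 3R started at positions 214 and 184. Merging peaks within 1000 bp joined 12 peaks at the tip of 3L into 1 region, from 214 to 19965.

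Peaks lay in clusters. Of the 15610 gaps between neighbouring peaks on the large arms, 68.2% were 5000 bp or shorter, against 52.0% ± 0.29 (SD) in 1000 random placements (ratio 1.31, one-sided permutation test by random placement, p = 0.001, the smallest that 1000 placements can give). Of the gaps, 33.5% were 1000 bp or shorter, against 13.3% in random placements. The direction turned for gaps of 20000 bp or shorter, which were 92.5% against 94.0% (ratio 0.983). Placements kept peak number and span, so more short gaps go with longer gaps elsewhere. Among the highest 50% of peaks by score, 52.5% of gaps were 5000 bp or shorter, against 29.6% in random placements (ratio 1.77). For the highest 25% the shares were 34.5% and 15.6% (ratio 2.22, permutation test by random placement, p = 0.001 in both sets, the smallest it can give). With fewer peaks the random share falls, so these ratios cannot be set against the 1.31 of the whole list. The median gap was 2180 bp. In windows of 100 kb the peak number was 13.2 ± 9.5 (SD, n = 1184 windows), and 52 windows held more than 32 peaks, the highest number reached in any window of any random placement. These 52 windows held 12.9% of the peaks of the large arms in 4.39% of the windows. At the other extreme, 63 windows held 0 peaks, where random placement gave at most 1 such window. Random placement took every position of a span as equally open to a peak. Whether peaks could be called at every position was not examined, so clusters and empty windows need not come from binding alone.

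The densest 100 kb windows were on 2R, 3R and 3L. The window of 2R from 7359208 to 7459207 held 55 peaks, that of 3R from 12700184 to 12800183 held 53, and that of 3L from 10900214 to 11000213 held 50. Among 1 Mb windows, 3R from 12000184 to 13000183 led with 306 peaks, followed by the distal window of 2R from 20059208 to 21059207 with 250 and by 3L from 1000214 to 2000213 with 237. On X no 1 Mb window exceeded 156 peaks.

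**Figure D4:**
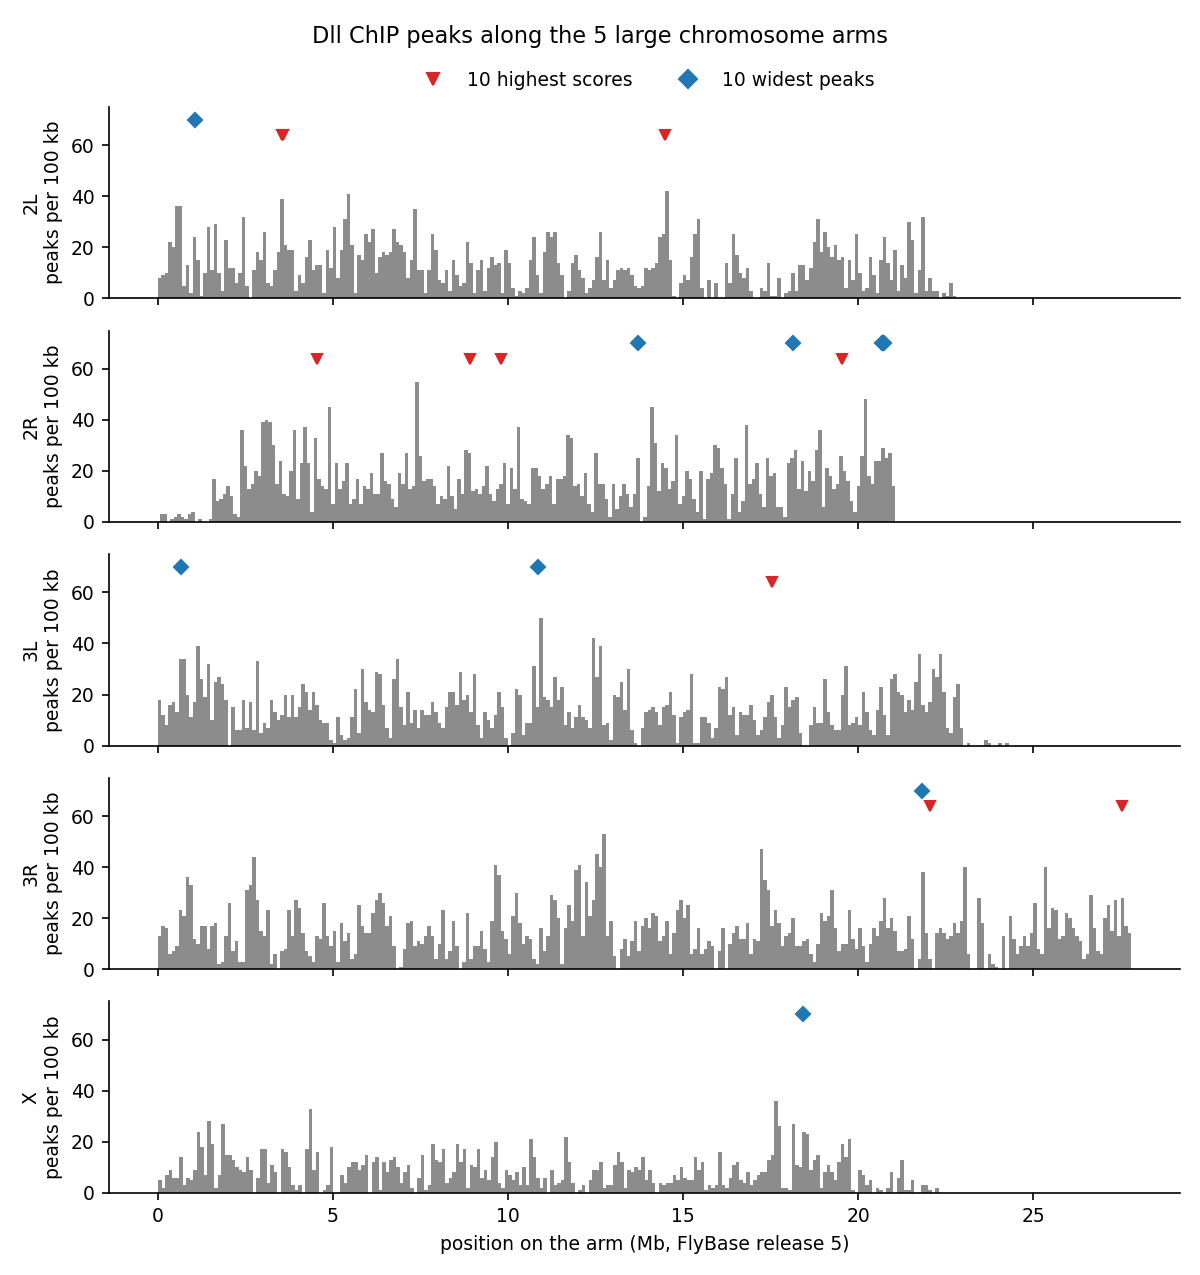
Peaks along the 5 large arms. Bars give the number of peaks per 100 kb window (y axis) by position in Mb on FlyBase release 5 (x axis); red triangles mark the 10 highest peaks and blue diamonds the 10 widest, and markers of peaks close to each other overlap. The window with the most peaks, 55, is on 2R.

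Peaks with close neighbours had higher scores and were wider. The 8383 arm peaks with another within 1000 bp had a median score of 18.47 (interquartile range 12.23 to 37.99), and the 7262 others had 15.80 (11.03 to 31.29; permutation test, two-sided, p = 1e-05, the smallest it can give). This test treats peaks as independent. The median widths of the same sets were 480 and 394 bp. Distances were measured between the edges of peaks, so for the same distance between centres wider peaks count as closer. As scores rose with width, part of both differences can come from this measure. Scores of neighbours were weakly related across pairs of peaks, which are not independent replicates, with a Spearman correlation of 0.265 (Pearson correlation of log10 scores 0.220) for pairs up to 1000 bp apart. It was 0.117 for pairs 1000 to 5000 bp apart and 0.0709 for pairs 5000 to 20000 bp apart (permutation test, adjusted p = 0.00013 in each of these 3 classes, the smallest it can give). For 1177 pairs farther apart it was 0.0252 (permutation test, adjusted p = 0.39).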

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

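The tests of this part were chosen after the list was seen. The list contains 472 peaks on scaffolds outside the 6 chromosome arms, which no comparison of arms used, and which were picked out because they are a signal in data set aside from the main measurement. They make up 2.93% of the list. Of these, 347 were on Uextra and 51 on U, the collections of sequence not placed on a chromosome, and 74 were on scaffolds of mapped heterochromatin. Peaks of Uextra had a median score of 28.3 (interquartile range 17.5 to 51.2), above that of 2L, 2R, 3L and 3R, 16.70 (permutation test, adjusted p = 5e-05), while their median width of 347 bp was 0.796 times as large (permutation test, adjusted p = 6.7e-05). Peaks of U had a median score of 31.7, also above that value (permutation test, adjusted p = 0.00025). For the 74 peaks of mapped heterochromatin the median score was 19.7 (permutation test, adjusted p = 0.13). YHet held 2 peaks and XHet held 1. How many of these scaffolds are repeats or copies of arm sequence was not tested, since it needs the sequence.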

How the results depend on the processing

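The windows of 1 Mb and the tests of the centromere side, of spacing and of neighbours, with their alternatives, were chosen after the list was seen. Of 67 alternative values for 13 results, 49 stayed on the same side of their threshold or, without a test, within their interval or, for the peak number, within 1.5 times. By construction the highest 50% and 25% of peaks left 8088 and 4031 peaks, with median scores of 35.2 and 70.89. Their median widths were 626 and 809 bp. Merging within 1000 bp left 10861 regions and moved the median width to 546 bp and the median score, the highest of each region, to 19.11. The ratio of X stayed below 1 in the 6 alternatives run, from 0.629 by base pairs to 0.817 in the highest 25%. Merging ended the binomial call of 2L (0.986) and the highest 25% that of 3L (1.03). The low densities of X and 4 raise these ratios, as the expected numbers come from all arms. With 1 Mb windows, which do not count clustered peaks as independent, 2L (0.970), 3L (1.07) and 3R (1.11) no longer passed. By base pairs, which weigh each peak by its width, 2L moved to 0.894 and 2R to 1.32. Median widths were 414.5 bp on 2L and 454.5 bp on 2R, against 436 bp on all arms. Why widths differ between arms was not tested. The ratio of windows next to the centromere to the others, 0.515, passed with 1 or 3 windows and without each arm in turn, from 0.371 to 0.741. On the grid laid from the low-coordinate end, which misses up to 1 Mb next to the centromere of 2L, 3L and X, it was 0.653, and there it did not pass without 2R (0.785) or with 3 windows per arm (0.857). On both grids these tests treat neighbouring windows as independent. The excess of short gaps reversed when gaps up to 20000 bp were counted (0.983), where 92.5% of gaps stood against 94.0% in random placements. Placements kept peak number and span, so more short gaps go with longer gaps elsewhere. This reversal is thus no evidence against clustering by itself. Chromosome 4 has no value with its ends left out, as its span is too short, nor over 1 Mb windows, where it was not included. Alternatives for positions relative to genes, strength by class, gene lists, peaks per gene and motifs were not run. No paired analysis was possible because the list gives no values per library, and for the same reason no replicate could be left out. Depth is unknown, and peaks too weak for the calling threshold are missing from every density given here.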

Other observations

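The patterns in this part were seen before they were tested, and the bounds of 0.9 and 1.1 were set before the test values were computed. After the values were seen, the interval for X was widened to one over windows, which moved that outcome from excluded to open.

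Merging peaks within 1000 bp gave several long regions. Next to each other on 2R, 10 peaks joined into 33813 bp (20723341 to 20757153, highest score 223.95) and 11 peaks into 32550 bp (20686523 to 20719072, highest score 230.55), the longest merged regions of the list, which overlap the stretch of wide peaks already described. On 3R, 11 peaks joined into 18491 bp at 11933026 to 11951516 (highest score 296.01) and 11 into 15997 bp at 12765532 to 12781528. At the tip of 3L, the merged 19752 bp had a highest score of 27.14. In all, 3169 regions held more than 1 peak, together 52.3% of the list, and 14 held 10 or more.

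Fewer peaks per Mb were found on X than on the autosomal arms. A few long empty stretches of X are argued against, since the median window of X held 0.596 times the peaks of the median window of 2L, 2R, 3L and 3R (95% bootstrap interval over windows 0.467 to 0.727), where 0.9 or more was needed. A loss of only the weak peaks near the threshold stays open. In the highest class of score X still had 0.815 times the expected peaks, and the exact interval (0.755 to 0.877) meets the bound of below 0.9 that was set to exclude this explanation. That bound was wrong for such an interval, which treats clustered peaks as independent, and the bootstrap interval over windows (0.690 to 0.938) reaches past 0.9. In the top 10% of the list the ratio of X was 0.902 (exact interval 0.805 to 1.01). In the top 1% it was 0.925 (0.631 to 1.28). These ratios lie above 0.9, where a loss of only weak peaks would put them. Their intervals reach to either side of 0.9, so they do not settle the question. The sex of the animals, the number of X copies and the share of reads on X were not examined. No biological explanation was tested.

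Peaks lay closer together than random placement gives. The splitting of 1 bound region into several peaks by the caller is argued against as the whole cause, as far as pieces within 1000 bp go: after merging, the share of gaps of 5000 bp or less was still 1.45 times the random one, 52.1% against 36.0%, and above all 1000 placements. Differences in density between 100 kb windows are argued against as the whole cause. With peaks placed at random inside their own window the share was 61.6% ± 0.263 (SD, 300 placements, highest 62.3%) against 68.2% observed, so the ratio fell from 1.31 to 1.11, just above the bound of 1.1 (lower limit 1.097, which a stricter margin tried after the values were seen would leave open). Such differences as part of the cause, and those over shorter distances, stay open, and no biological explanation was tested.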
